A study of Mus musculus with 4 samples.

How the data were processed

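The data were RNA sequencing libraries of YFP-positive erythroid cells sorted from mouse fetal livers at embryonic day 14.5, with 2 libraries labelled knockout (Adar deleted by Cre recombinase under the Epor gene) and 2 labelled wild type. The authors deposited raw counts per gene, which are whole numbers, in a table of 10716 genes. The deposited normalised values are CPM (counts scaled to a common library size) of the TMM-scaled library, and their ratio to plain CPM varied by at most 0.098% within a library, as rounding gives. The deposited comparison table holds the authors' log2 fold change, coded as wild type minus knockout, whose sign was turned here, and the authors' p-value and adjusted p-value for each gene. The submitters' processing notes name Trimmomatic 0.30, TopHat2 2.0.8, Bowtie2 2.1.0.0, SAMtools 0.1.19, BWA 0.6.2, HTSeq, Cufflinks, edgeR, limma and GATK, with the builds mm9 and NCBIM37, without giving the role of each. The strand of the libraries and the treatment of reads shared between paralogs are not stated.

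In the deposited table every gene exceeded 1 CPM in at least 2 libraries, so genes below that level cannot be seen. A gene below it in both libraries of a group is in the table only through the other group. The table gave 15 gene names as dates, which were kept as written, and 1117 genes had no Ensembl identifier. Positions, GC content and transcript lengths came from an annotation on NCBIM37, in which 9537 genes were found and 9310 had GC content and length. Total counts ran from 28356401 to 44016809 per library. Intervals and floors cover counting error only, and the floor for a count of 0 was 3 counts per library.

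Libraries were grouped by their titles and descriptions, which call 2 of them knockout. Per the labels the genotype of those 2 is Epor-Adar / +, which leaves open whether 1 or both Adar alleles were deleted, and that of the controls is wild type. The comparison was knockout-labelled against control, fitted in edgeR 4.0.16 under R 4.3.3 with filterByExpr, TMM scaling, estimateDisp, glmQLFit with robust=TRUE and the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The filter removed 0 genes, and 2 residual degrees of freedom were left. The legacy option of glmQLFit was not named when the design was fixed, so the package default (TRUE) was used. That was settled when the counts under both values of the option had been seen, and the other value (FALSE) is given as an alternative. The standard error of a log2 fold change was its absolute value divided by the square root of F. The common biological coefficient of variation was 25.6%. Values per library are CPM of the TMM-scaled library, given with the SD of 2 libraries per group, and list medians per library used log2 CPM with a prior count of 2.

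The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Adar, up to 10 genes in each direction with the largest log2 fold change among those past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap, and for each list its 3 members with the smallest p among those past the threshold over all genes, or the 1 member with the smallest p where none passed. The member that the rule takes from 1 list is not reported here. Genes whose groups do not overlap numbered 5789 (54%), where chance gives 33.3%.

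There were 34 gene lists, covering interferon-stimulated genes, RNA sensing, interferon receptors, MHC class I presentation, inflammatory genes, globins, haem, erythroid transcription factors and membrane genes, other cell types, p53 and stress responses, cell death, cell cycle, ribosomes, editing, transposable-element regulators, metabolism, autophagy, histones, immediate-early genes, mitochondrially encoded genes and sex-linked genes. Of the mitochondrially encoded list 0 genes were in the table. The 31 lists with at least 5 measured genes and a group question were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera called 21 lists, 15 higher and 6 lower. With an estimated correlation 0 of the 31 lists passed (adjusted p from 0.29 to 0.84), and with fry 0 passed for a shared direction or for change in either direction. Both tests rest on the 2 residual degrees of freedom, so their 0 does not show that a list is unchanged. The preset correlation was not estimated from these libraries, so neither setting settles which lists differ. Counts of members are given over all genes tested and adjusted over the list alone.

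The alternatives were RLE scaling, no library scaling, no filter on low counts, DESeq2 1.42.0, limma-voom and edgeR's likelihood ratio test. Also used were robust=FALSE, legacy=FALSE, sex as a covariate and leaving out each library in turn. A stricter filter kept genes with at least 1 CPM in every library of at least 1 group. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The quasi-likelihood test was also tested on simulated data with the depths and spread of these libraries and 50 changed genes at each fold. It recovered 26% of genes changed 2-fold, 88% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. These were 13, 44, 50 and 50 genes, beside 21 unchanged genes called. Simulated counts were drawn separately for each gene, without a shift across many genes such as that of knockout-labelled replicate 1. The rates therefore do not carry over to the real libraries. There Oas2, an example chosen after its values were seen, did not pass at a log2 fold change of 7.78 (edgeR adjusted p = 0.176).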

Results

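RNA was sequenced from erythroid cells of C57BL/6 mouse fetal livers at embryonic day 14.5, sorted by flow cytometry for YFP fluorescence. There were 2 libraries labelled knockout (replicates 1 and 2), in which Cre recombinase under the erythropoietin receptor gene acts on Adar, and 2 libraries labelled wild type (replicates 3 and 8), called controls here. The genotype field of the knockout-labelled libraries reads Epor-Adar / +, which does not say whether both Adar alleles were deleted. The gene table held 10716 genes, and its total counts were 32452155 and 38124687 in knockout-labelled replicates 1 and 2, and 28356401 and 44016809 in control replicates 3 and 8. Globin genes took 5.88% and 5.69% of the counts in the knockout-labelled libraries and 8.67% and 5.96% in the controls. The comparison asks which transcripts differ in erythroid cells when Adar, the gene of the RNA-editing enzyme ADAR1, is deleted.

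Adar (ENSMUSG00000027951, chromosome 3 of NCBIM37, 89518944 to 89557368, plus strand) had normalised read counts of 67.1 and 102 CPM (counts scaled to a common library size) in the knockout-labelled libraries and 50.9 and 46.9 in the controls. The means were 84.4 ± 24.4 and 48.9 ± 2.82 CPM (SD, n = 2 each), and the log2 fold change was 0.79 (SE 0.25, edgeR adjusted p = 0.377). Without knockout-labelled replicate 1 it was 1.06 (adjusted p = 0.0130). A gene-level count also covers exons that a conditional allele keeps, so this value tests nothing about a partial deletion, and the labels do not name the deleted exons.

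The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in each library as a check of the sex labels. Eif2s3y (chromosome Y, 346986 to 365290) had 106 CPM in knockout-labelled replicate 1, which is labelled female, and 0 counts in knockout-labelled replicate 2, which is labelled male. A count of 0 allows up to 0.0778 CPM in that library (3 counts), for counting error only. The same gene had 72.2 in control replicate 3, labelled female, and 79.6 in control replicate 8, labelled male. The Y-linked counts went against the sex label in 3 of the 4 libraries, and Xist was not among the genes of the table.

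**Figure D1:**
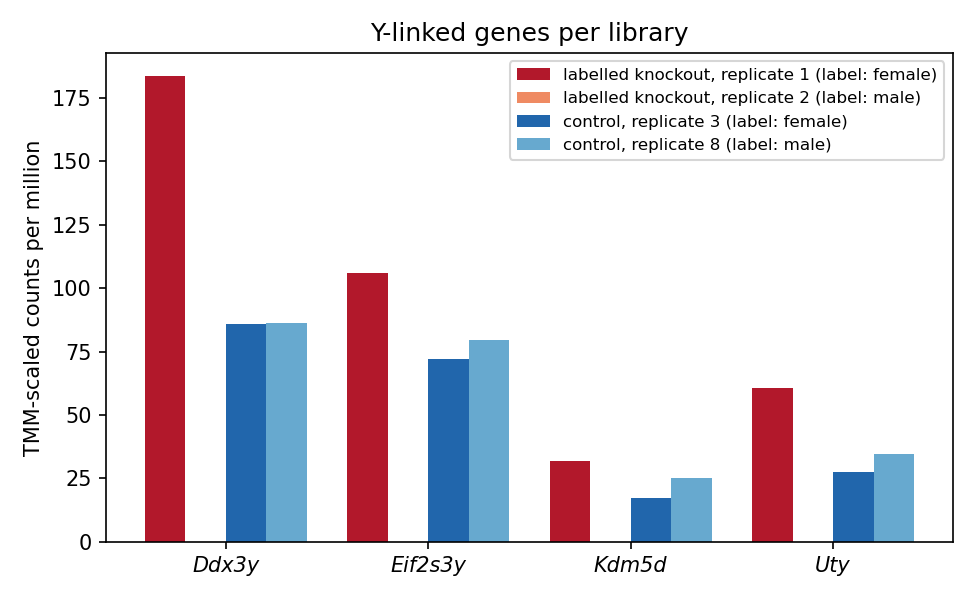
CPM of the TMM-scaled library (y axis, linear) of 4 Y-linked genes (x axis) in each of the 4 libraries, with the sex each label gives in the legend; each bar is 1 library. Knockout-labelled replicate 2, labelled male, had 0 counts of Eif2s3y, Kdm5d and Uty and 3 counts of Ddx3y, while the other libraries had 17.3 to 184 CPM.

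Members of the lists of interferon-stimulated genes and of targets of the transcription factor ATF4 made up 9 of the 11 genes that passed (5 and 4). The others, on neither list, were 9230105E10Rik and Oas1b, whose family members Oas1a, Oas1g, Oas2 and Oas3 are on the interferon list. Each of the 11 was higher in both knockout-labelled libraries than in both controls. Oas3, a synthetase of the RNase L activator oligoadenylate, had 102 ± 34.9 CPM in the knockout-labelled libraries and 0.254 ± 0.000202 in the controls (SD, n = 2 each). The control values of Oas3 were 7 and 12 counts, so their counting error is larger than that SD. Isg15, a ubiquitin-like modifier, had 359 ± 200 against 3.0 ± 0.118, and Rsad2, the antiviral protein viperin, had 197 ± 33.3 against 6.67 ± 0.618. Trib3, a pseudokinase induced under stress, had 191 ± 53 against 6.46 ± 1.99, and Atf5, a transcription factor of the stress response, had 106 ± 2.81 against 13.6 ± 2.86.

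The edgeR quasi-likelihood test called 11 of 10716 genes at an adjusted p below 0.05, and all 11 were higher in the knockout-labelled libraries. Oas3 (ENSMUSG00000032661) had the largest log2 fold change, 8.63 (SE 0.41, adjusted p = 0.00663). The log2 fold changes were, for Isg15 (ENSMUSG00000035692), 6.90 (SE 0.51), for Oasl2 (ENSMUSG00000029561) 5.19 (SE 0.39), for Trib3 (ENSMUSG00000032715) 4.89 (SE 0.35) and for Atf5 (ENSMUSG00000038539) 2.96 (SE 0.23), each with an adjusted p of 0.027. Rsad2 (ENSMUSG00000020641) rose by 4.88 (SE 0.25, adjusted p = 0.00663), and Lgals3bp (ENSMUSG00000033880), a secreted glycoprotein, by 5.16 (SE 0.48, adjusted p = 0.0436). Oas1b (ENSMUSG00000029605) rose by 4.26 (SE 0.37), the cystine transporter gene Slc7a11 (ENSMUSG00000027737) by 3.85 (SE 0.35) and the transcription factor gene Cebpb (ENSMUSG00000056501) by 2.70 (SE 0.24), each with an adjusted p of 0.043. The last called gene, 9230105E10Rik, fell outside the naming rule and was chosen after its values were seen, with a log2 fold change of 2.54 (SE 0.24, adjusted p = 0.0483).

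On NCBIM37, chromosome 5 holds Oasl2 from 115346943 to 115362243, Oas3 from 121203107 to 121227670 and Oas1b from 121262644 to 121274186. No position was found for 9230105E10Rik. Trib3 (152163158 to 152169768) and Cebpb (167514415 to 167515918) are on chromosome 2, and Slc7a11 (50168858 to 50247535) is on chromosome 3. Isg15 is on chromosome 4 (155573533 to 155574927), Atf5 on chromosome 7 (52067627 to 52072028), Lgals3bp on chromosome 11 (118254065 to 118263406) and Rsad2 on chromosome 12 (27127618 to 27141317). Members of the Oas family have similar sequences, and how reads shared between them were counted is not stated.

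**Figure D2:**
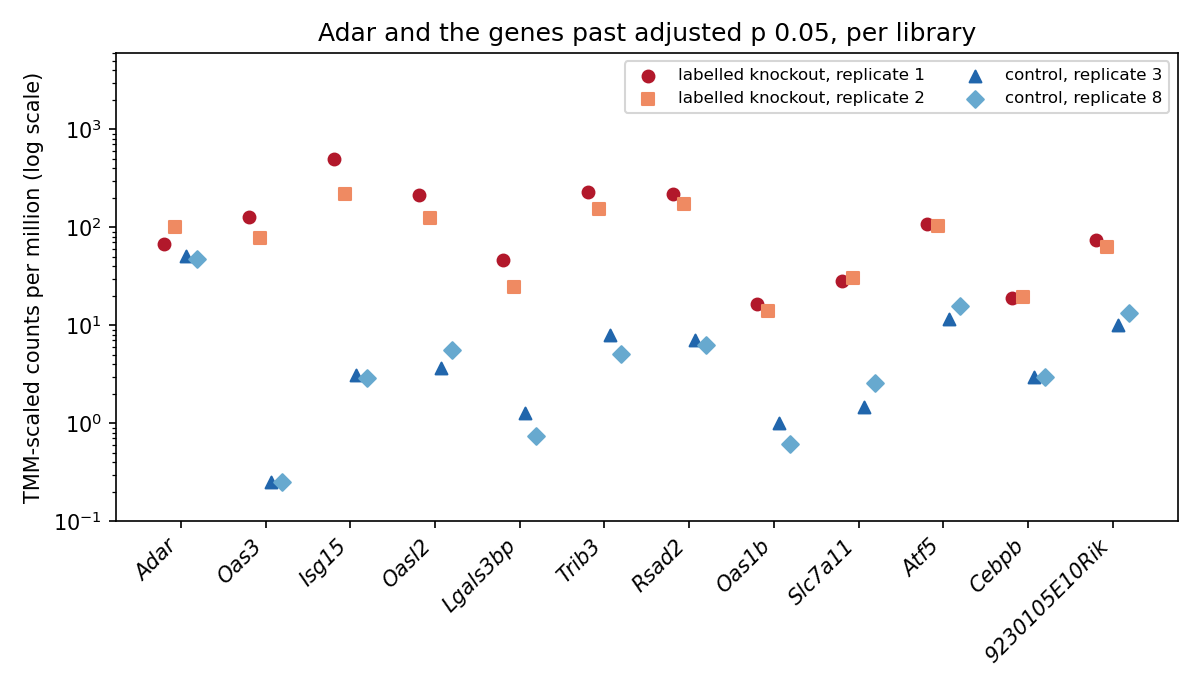
CPM of the TMM-scaled library (y axis, log scale) of Adar and the 11 called genes (x axis); each point is 1 library. For each called gene both knockout-labelled libraries lie above both controls, with Oas3 at 77.5 and 127 CPM against 0.254 in each control.

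No gene passed as lower in edgeR's quasi-likelihood test, where 223 genes had lower values at an unadjusted p below 0.05 and the smallest adjusted p among lower genes was 0.152. On the same genes DESeq2 called 21 lower, edgeR's likelihood ratio test 18 and limma-voom 0. At an unadjusted p below 0.05 there were 1275 genes, 1052 of them higher, and in 1183 of the 1275 knockout-labelled replicate 1 lay farther from the control mean than replicate 2. The 11 calls became 143 without knockout-labelled replicate 1, 3492 without knockout-labelled replicate 2, 41 without control replicate 3 and 27 without control replicate 8. Each of these sets held all 11 genes, except that without control replicate 8, which held 10. The p-values measure only the spread between these 4 libraries, since the labels do not say whether each came from a separate embryo.

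Of 54 measured type I interferon-stimulated genes, 5 rose over all genes tested and 47 rose when adjusted over the list alone, with none lower except without knockout-labelled replicate 2 (4 lower). The 5 became 36 without knockout-labelled replicate 1, 48 without replicate 2, 18 without control replicate 3, 10 without control replicate 8, 24 with sex as a covariate, 26 without library scaling, 40 with DESeq2 and 41 with the likelihood ratio test. Beyond the called members, Ifi27l1 was 6.13 higher on the log2 scale (SE 0.61), Oas1a 7.44 (SE 0.80) and Parp14 3.05 (SE 0.31) in that count, and these examples, like others named below as examples, were chosen after their values were seen. Adar itself is one of the members counted. The 7 members that did not pass were Slfn5, Znfx1, Ifit2, Pml, Irgm2, Ly6e and Ube2l6, with log2 fold changes from -0.61 (Znfx1) to 0.64 (Slfn5). The list median was 2.82, with 3.26 in knockout-labelled replicate 1 and 2.1 in replicate 2, and camera placed the list higher than other genes (adjusted p = 6.31e-90). That p was 0.47 as an adjusted p with an estimated correlation.

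Sensors of double-stranded RNA and their signalling genes numbered 22, of which 2 rose over all genes and 11 adjusted over the list alone. The 2 became 11 without knockout-labelled replicate 1, 14 without replicate 2, 5 without control replicate 3, 8 with sex as a covariate, 6 without library scaling, and 10 with DESeq2 and with the likelihood ratio test. Of those 11, 10 are also on the interferon-stimulated list, among them the cytosolic sensor genes Ifih1 (log2 fold change 2.14, SE 0.22) and Ddx58 (4.63, SE 0.77). The adaptor gene Mavs (-0.05), the kinase gene Tbk1 (-0.08) and Irf3 (-0.57) did not pass. The list lay higher in camera (adjusted p = 1.51e-19), against an adjusted p = 0.291 with an estimated correlation. Its median was 0.57 and 0.68 in knockout-labelled replicates 1 and 2.

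Of the interferon ligand and receptor list 8 genes were measured, namely Ifnar1, Ifnar2, Ifngr1, Ifngr2, Il10rb, Jak1, Tyk2 and Socs3. These are receptor and signalling genes, and no interferon gene of the list was measured. None of the 8 passed in edgeR's quasi-likelihood test, over all genes or adjusted over the list alone. Camera did not separate the list (adjusted p = 0.42). Adjusted over the list alone, DESeq2 and edgeR's likelihood ratio test each gave 1 higher, as did the fits without library scaling and without knockout-labelled replicate 1. The fit with sex as a covariate gave 1 higher and 1 lower, and the fit without knockout-labelled replicate 2 gave 2 higher and 1 lower. Ifnar2, a subunit of the type I interferon receptor, had the smallest p, with a log2 fold change of 0.95 (SE 0.23, adjusted p = 0.299). In the MHC class I presentation list of 17 genes, 0 rose over all genes and 4 adjusted over the list alone. These were Psme1 (1.05, SE 0.23), B2m (1.97, SE 0.46), H2-D1 (1.57, SE 0.39) and Tap1 (3.12, SE 0.77). The count was 10 without knockout-labelled replicate 2, 0 without control replicate 3 and 1 without control replicate 8. Camera gave an adjusted p = 0.00216 for the list, and an adjusted p = 0.615 with an estimated correlation.

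Of 9 inflammatory cytokine and NF-kB target genes, 0 rose over all genes and 3 adjusted over the list alone (5 without knockout-labelled replicate 2). They were Relb (log2 fold change 3.39, SE 0.56), the chemokine gene Cxcl10 (4.17, SE 0.74) and the NF-kB inhibitor gene Nfkbia (1.92, SE 0.52). Cxcl10 had 2.35 and 1.04 CPM in the knockout-labelled libraries and 0.036 and 0.127 in the controls. It is thus in the table only through the knockout-labelled libraries. Camera gave an adjusted p = 0.000766 for this list, and an adjusted p = 0.536 with an estimated correlation.

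Integrated stress response and ATF4 target genes numbered 38, of which 4 rose over all genes (Trib3, Atf5, Cebpb and Slc7a11) and 19 adjusted over the list alone. The 4 became 11 without knockout-labelled replicate 1, 22 without replicate 2, 8 without control replicate 3, 10 without library scaling, 19 with DESeq2 and 17 with the likelihood ratio test. Among the 19 were Ddit3, which encodes CHOP (log2 fold change 1.74, SE 0.28), the proline synthesis gene Pycr1 (1.99, SE 0.30), Nupr1 (4.76, SE 0.78) and Sesn2 (1.81, SE 0.22). Atf4 itself (0.43), the asparagine synthetase gene Asns (0.60) and 17 others did not pass. The median was 1.03 in knockout-labelled replicate 1 and 0.57 in replicate 2, and camera placed the list higher (adjusted p = 8.1e-28). With an estimated correlation the adjusted p = 0.47. Chaperones of the unfolded protein response, 19 genes, had 0 members past either threshold in edgeR's quasi-likelihood test. Ern1, the stress sensor kinase IRE1, had a log2 fold change of 1.22 (SE 0.29, adjusted p = 0.295), and the chaperone gene Hspa5 had 1.40 (SE 0.56). Camera placed this list higher (adjusted p = 0.0364), against an adjusted p = 0.653 with an estimated correlation, 0.563 without knockout-labelled replicate 1 and 0.0607 without control replicate 8.

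Of 17 immediate-early and heat-shock genes, none passed over all genes, where the unadjusted smallest p belonged to Atf3 (log2 fold change 3.81, SE 0.71, adjusted p = 0.189). Adjusted over the list alone, 5 rose (Atf3, Jund, Jun, Zfp36 and the heat-shock gene Hspa1a) and Ier3 fell by 1.03 (SE 0.31). The 5 became 2 without knockout-labelled replicate 1, 8 without replicate 2, 1 without control replicate 3, 1 without control replicate 8 and 0 with limma-voom. Hspa1a had 390 and 102 CPM in the knockout-labelled libraries and 3.73 and 32.4 in the controls. Camera gave an adjusted p = 0.00383 for the list, and an adjusted p = 0.582 with an estimated correlation.

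Targets of p53, 26 genes, had 0 members past the threshold over all genes and 10 that rose when adjusted over the list alone. They included Cdkn1a, the cell cycle inhibitor p21 (log2 fold change 2.91, SE 0.57), Bbc3, the cell death activator PUMA (2.80, SE 0.56), and Mdm2, which encodes the ubiquitin ligase of p53 (0.92, SE 0.27). Gdf15 had the smallest p (3.74, SE 0.44, adjusted p = 0.0747 over all genes), and Sesn2 is also on the ATF4 list. The count was 6 without knockout-labelled replicate 1, 20 without replicate 2 and 5 without control replicate 3. Camera placed the list higher (adjusted p = 1.53e-11), against an adjusted p = 0.536 with an estimated correlation, with medians of 1.27 and 0.40 in knockout-labelled replicates 1 and 2. The 26 cell death regulators had 0 members past either threshold, with Bbc3 leading (adjusted p = 0.219 over all genes). Their median and mean were positive (median 0.02) while camera leaned lower (adjusted p = 0.837), so no direction is given for this list. Camera leaned higher without knockout-labelled replicate 1 (adjusted p = 0.817), knockout-labelled replicate 2 (0.992) or control replicate 3 (0.853), as did fry (0.452), and the median was -0.04 without library scaling.

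Genes of the erythroid program did not pass in edgeR's quasi-likelihood test over all genes. Of 8 globin genes, the embryonic alpha-like globin Hba-x rose when adjusted over the list alone (log2 fold change 3.26, SE 0.64, adjusted p = 0.218 over all genes). Hba-x had 1303 and 384 CPM in the knockout-labelled libraries and 62.8 and 113 in the controls. That count of 1 was 2 without knockout-labelled replicate 1, 3 without replicate 2 and 0 without control replicate 3. The embryonic Hbb-y had a log2 fold change of 1.70 (SE 0.62), and the adult Hbb-b1 had -0.61 (SE 0.38) and Hba-a1 -0.15 (SE 0.39). Camera gave an adjusted p = 0.18 for the globin list, 0.0143 without knockout-labelled replicate 2 and 0.0021 without control replicate 3, higher in each, and an adjusted p = 0.653 with an estimated correlation.

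The haem synthesis and iron uptake list (27 genes), the erythroid transcription factors (24 genes) and the erythroid membrane and cytoskeleton list (33 genes) each had 0 members past either threshold in edgeR's quasi-likelihood test. Their median log2 fold changes were -0.01, -0.12 and -0.15, and camera gave adjusted p values of 0.42, 0.42 and 0.277. Without control replicate 3 these medians were 0.12, 0.02 and 0.03, without knockout-labelled replicate 2 they were -0.14, -0.30 and -0.33, and without knockout-labelled replicate 1 that of the transcription factors was 0.02. Without control replicate 8 the membrane list passed as lower (median -0.30, camera adjusted p = 0.00569), against an adjusted p = 0.799 with all libraries and an estimated correlation. The haem-degrading enzyme gene Hmox1 had a log2 fold change of 1.62 (SE 0.34, adjusted p = 0.25), and the repressor gene Mxi1 0.60 (SE 0.25). The entry named Cd47 had 0.65 (SE 0.26), but the annotation gives its identifier (ENSMUSG00000079488) as a pseudogene, so the value is not shown to be that of the surface protein gene. Klf1, a master regulator of erythroid genes, had 204 and 520 CPM in knockout-labelled replicates 1 and 2 and 689 and 533 in the controls (-0.75, SE 0.45).

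Glycolysis and hypoxia response genes numbered 24, with 0 past the threshold over all genes and 19 that rose when adjusted over the list alone. The hypoxia-induced genes Ndrg1 (log2 fold change 3.71, SE 0.71, adjusted p = 0.2 over all genes) and Vegfa (2.74, SE 0.59), the glycolytic gene Pgk1 (2.06, SE 0.47) and the mitophagy receptor gene Bnip3 (3.43, SE 0.75) were among them. The 19 became 0 without control replicate 3, 13 without control replicate 8 and 13 without knockout-labelled replicate 1. The controls differed in this list by a median of -0.57 (replicate 3 minus replicate 8), and the medians were 2.01 and 1.06 in knockout-labelled replicates 1 and 2. Camera placed the list higher (adjusted p = 2.07e-15), against an adjusted p = 0.556 with an estimated correlation.

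Of 24 autophagy and mitochondrial clearance genes, 3 rose when adjusted over the list alone: Bnip3, Sqstm1 (log2 fold change 0.96, SE 0.22) and Optn (0.75, SE 0.18). None passed over all genes. The 3 became 0 with RLE scaling, without library scaling, with limma-voom, with sex as a covariate and without knockout-labelled replicate 1, control replicate 3 or control replicate 8, and 13 without knockout-labelled replicate 2. Camera gave an adjusted p = 0.000411 for the list, and an adjusted p = 0.615 with an estimated correlation. Sterol and fatty acid synthesis genes (24) had 0 members past either threshold, with Scd1, a fatty acid desaturase gene, at -0.95 (SE 0.29, adjusted p = 0.363). Camera placed this list lower (adjusted p = 0.00208), against an adjusted p = 0.47 with an estimated correlation, and its median was -0.32.

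Cell cycle lists were lower as sets while no member passed either threshold in edgeR's quasi-likelihood test. For 30 S-phase genes, led by the replication factor gene Gins2 (log2 fold change -0.36, SE 0.20, adjusted p = 0.447), the median was -0.31 and camera gave an adjusted p = 0.000564. That became an adjusted p = 0.653 with an estimated correlation and 0.182 without knockout-labelled replicate 1. The S-phase medians were -0.55 and -0.07 in knockout-labelled replicates 1 and 2, and the list median was -0.07 without replicate 1 and -0.57 without replicate 2. For 30 G2 and M-phase genes, led by the cyclin gene Ccnb1 (-0.55, SE 0.23, adjusted p = 0.427), the median was -0.38 (camera adjusted p = 0.000308). With an estimated correlation that adjusted p = 0.653. The G2 and M-phase medians were -0.56 and -0.19 in knockout-labelled replicates 1 and 2, and the list median was -0.19 without replicate 1, -0.58 without replicate 2 and -0.22 without control replicate 3.

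All 40 ribosomal protein genes had positive log2 fold changes, with a median of 0.56, and none passed either threshold in edgeR's quasi-likelihood test. Rpl5 had the smallest p (1.37, SE 0.39, adjusted p = 0.354), and camera placed the list higher (adjusted p = 1.74e-09). With an estimated correlation the list's adjusted p = 0.653. The ribosomal protein medians were 0.81 and 0.28 in knockout-labelled replicates 1 and 2, and the list median was 0.26 without replicate 1. The 30 ribosome biogenesis genes had 0 members past either threshold and a median of -0.37, with Bop1 at -0.86 (SE 0.29, adjusted p = 0.391). Camera placed them lower (adjusted p = 0.000298), against an adjusted p = 0.653 with an estimated correlation and 0.120 without control replicate 8. The biogenesis median was -0.25 without knockout-labelled replicate 1 and -0.22 without control replicate 8.

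Among markers of other cell types, no member passed over all genes in edgeR's quasi-likelihood test. The 12 macrophage genes had a median of -1.44, with -1.78 and -0.84 in knockout-labelled replicates 1 and 2, and the median of control replicate 3 minus control replicate 8 was 1.05. The list median was -0.95 without knockout-labelled replicate 1 and -0.66 without control replicate 3. The adhesion gene Vcam1 had a log2 fold change of -2.70 (SE 0.61, adjusted p = 0.278). It exceeded 1 CPM only in the controls, so it is in the table through them. Camera placed the list lower (adjusted p = 4.09e-05). With an estimated correlation that adjusted p = 0.615. None of these members passed when adjusted over the list alone, where DESeq2 gave 6 lower. Without control replicate 8 that count was 7 lower, and without knockout-labelled replicate 2 it was 8 lower and 1 higher.

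The 10 granulocyte and monocyte genes had medians of 2.89 in knockout-labelled replicate 1 and -0.19 in replicate 2, and 0 members passed either threshold in edgeR's quasi-likelihood test. S100a9, a calcium-binding protein gene of neutrophils, had 113 CPM in knockout-labelled replicate 1 and 12.6, 11.7 and 15.1 in knockout-labelled replicate 2 and the controls (adjusted p = 0.425). Camera placed the list higher (adjusted p = 0.00709), against an adjusted p = 0.653 with an estimated correlation. Without knockout-labelled replicate 1 the list leaned lower (adjusted p = 0.217) and the log2 fold change of S100a9 was -0.09.

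The 16 megakaryocyte and platelet genes had medians of 1.77 and 0.41 in knockout-labelled replicates 1 and 2 and 0 members past either threshold, with Treml1 at 1.78 (SE 0.47, adjusted p = 0.325). Camera placed this list higher (adjusted p = 1e-04), against an adjusted p = 0.615 with an estimated correlation. Of 12 endothelial and stromal genes, 2 rose when adjusted over the list alone, the endothelial surface gene Pecam1 (2.49, SE 0.55) and the VEGF receptor gene Kdr (1.20, SE 0.30). That count was 5 without knockout-labelled replicate 1, 0 without control replicate 3, 1 without control replicate 8 and 0 with limma-voom. Camera gave an adjusted p = 0.00226 for the list, an adjusted p = 0.47 with an estimated correlation and 0.158 without knockout-labelled replicate 2.

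The 13 hepatoblast and hepatocyte genes had a median of -0.57 and 0 members past either threshold, with Apoa2 at -1.02 (SE 0.53, adjusted p = 0.439). Camera placed this list lower (adjusted p = 0.0216), against an adjusted p = 0.653 with an estimated correlation, 0.218 without knockout-labelled replicate 1 and 0.071 without replicate 2. Without control replicate 3 it leaned higher (median 0.20, adjusted p = 0.847). The median was -0.28 without knockout-labelled replicate 1, -1.05 without replicate 2 and -1.17 without control replicate 8. The 12 stem and progenitor genes had 0 members past either threshold, and camera gave an adjusted p = 0.211. Of the lymphoid list 1 gene was measured, the T cell kinase gene Lck (-0.38, SE 0.34, adjusted p = 0.575).

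The 6 RNA-editing enzyme genes had 0 members past either threshold, and the cytidine deaminase gene Apobec1 had a log2 fold change of 2.13 (SE 0.56, adjusted p = 0.325). The 18 transcripts with known A-to-I edited sites also had 0, with Tcea1 at 0.86 (SE 0.26, adjusted p = 0.355), and so did the 19 transposable-element and heterochromatin regulators, with the helicase gene Mov10 at 0.96 (SE 0.27, adjusted p = 0.346). Camera gave adjusted p values of 0.42, 0.389 and 0.286 for these lists. Editing levels were not analysed here.

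Beside the lists with 0 members past the threshold over all genes in edgeR's quasi-likelihood test, limma-voom also gave 0, and other counts differed. At an unadjusted p below 0.05 the quasi-likelihood test had 19 of 24 glycolysis and hypoxia genes, 13 of 26 p53 targets, 8 of 17 immediate-early genes, 6 of 17 MHC class I genes and 5 of 9 inflammatory genes, of which DESeq2 called 15, 7, 2, 4 and 3 over all genes and the likelihood ratio test 15, 7, 3, 4 and 3. It had 3 globin, 3 haem, 3 interferon receptor, 2 cell death and 4 unfolded protein response genes, of which DESeq2 called 3, 2, 1, 1 and 2 and the likelihood ratio test 2, 1, 1, 1 and 2. It had 7 megakaryocyte, 6 macrophage, 3 endothelial, 6 autophagy, 8 ribosomal protein, 3 editing enzyme and 5 histone genes, of which DESeq2 called 1, 2, 2, 2, 1, 1 and 3 and the likelihood ratio test 1, 2, 1, 2, 1, 1 and 1. It had 6 sterol, 4 ribosome biogenesis, 3 edited-transcript, 2 transposable-element regulator and 1 erythroid membrane genes, and 0 erythroid transcription factor, S-phase, G2 and M-phase, granulocyte and hepatocyte genes, and for these lists DESeq2 and the likelihood ratio test called 0 over all genes. Adjusted over the list alone, where the quasi-likelihood test gave 0, DESeq2 and the likelihood ratio test gave 7 and 8 megakaryocyte genes, 6 and 6 macrophage genes, 3 and 8 granulocyte genes and 4 and 3 unfolded protein response genes. There the interferon receptor and cell death lists had 1 higher by each of these tests, the haem list 1 higher and 1 lower by each, and the editing enzymes 2 higher by each and 1 lower by DESeq2. DESeq2 alone gave 1 ribosomal protein gene and 3 edited transcripts.

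Without knockout-labelled replicate 2, where 3492 genes passed, each list with 0 members over all genes had between 1 (hepatocyte) and 19 (glycolysis and hypoxia). Without knockout-labelled replicate 1 there were 4 p53 targets, 2 inflammatory genes, 2 glycolysis and hypoxia genes and 1 gene each of the MHC class I, haem, cell death, editing enzyme and immediate-early lists. Without control replicates 3 and 8 there were 3 and 1 p53 targets. Adjusted over the list alone, the fit without knockout-labelled replicate 2 also gave 15 S-phase, 12 G2 and M-phase and 12 ribosome biogenesis genes lower, and 10 granulocyte, 11 megakaryocyte and 9 unfolded protein response genes higher. It gave 5 erythroid transcription factor genes higher and 8 lower.

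**Figure D3:**
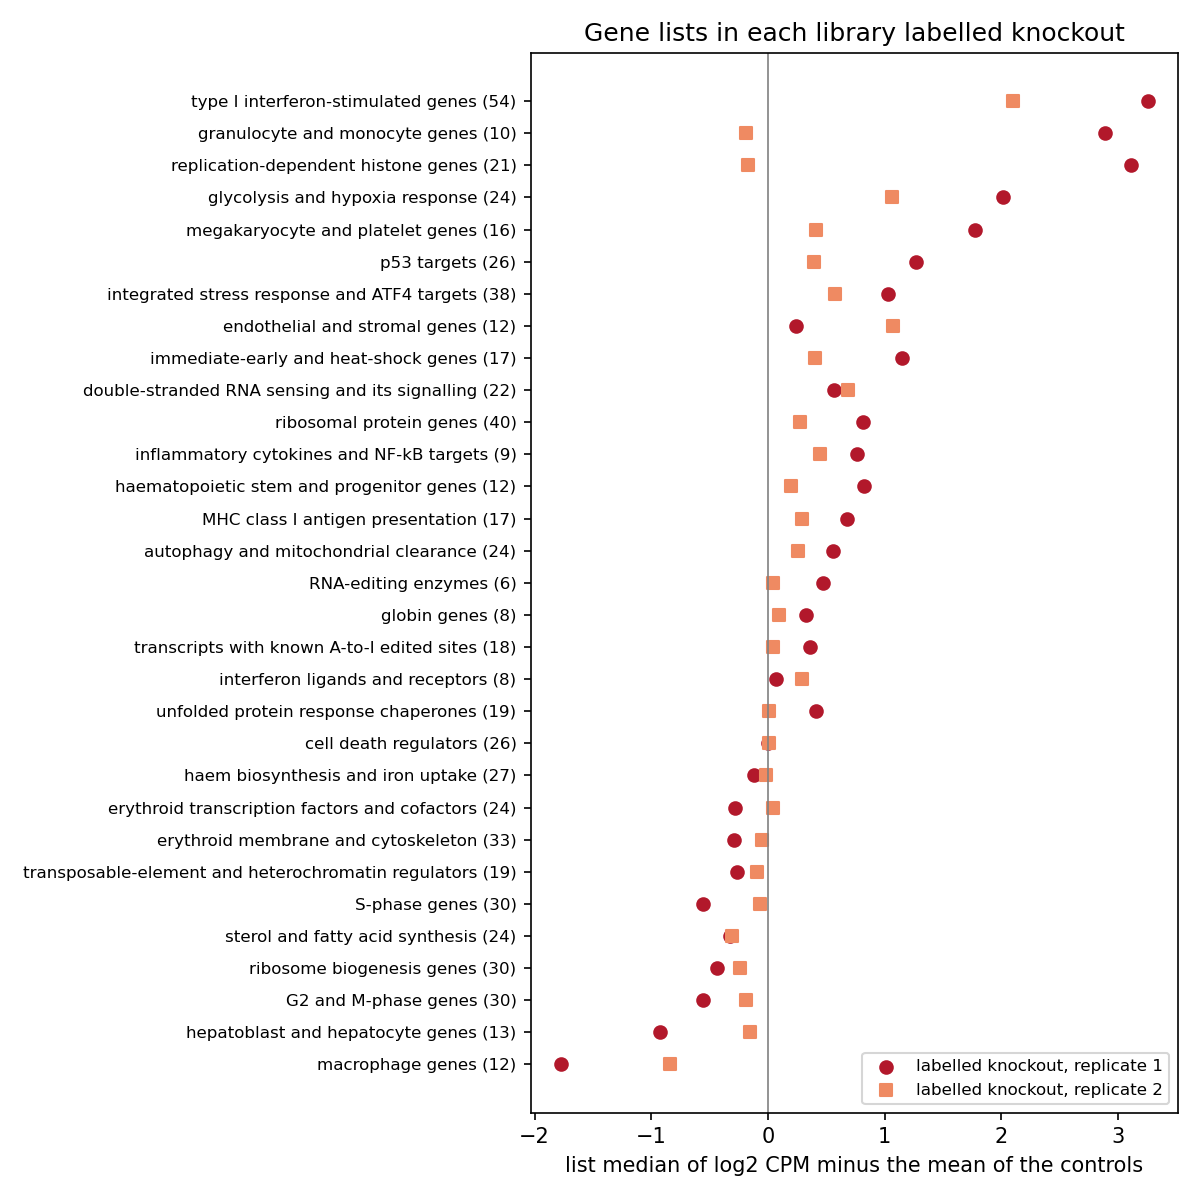
Median over each list's measured genes of log2 CPM minus the mean of the controls (x axis) in each knockout-labelled library, for the lists tested (y axis, number of genes in parentheses). The interferon-stimulated list lay at 3.26 and 2.1, while granulocyte and histone genes lay far above 0 in replicate 1 only.

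The authors' deposited comparison of the same libraries held 8 genes at an adjusted p below 0.05, all higher in knockout and all among the 11. They were Rsad2, Trib3, Oas3, Atf5, Oasl2, Isg15, Slc7a11 and Oas1b. Across the 10716 genes, which are not independent replicates, the authors' log2 fold changes and those fitted here had a Pearson r of 0.981, and 98.5% had the same sign.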

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

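Tests chosen only after the result was seen were the quasi-likelihood fit with legacy=FALSE and the counts adjusted over each list alone under each alternative. The 11 calls were 11 with RLE scaling or without the filter, 8 with limma-voom and 15 with the stricter filter, robust=FALSE or legacy=FALSE, all higher. Without library scaling there were 87 (85 higher, 2 lower), with DESeq2 374 (353 higher, 21 lower), with the likelihood ratio test 349 (331 higher, 18 lower) and with sex as a covariate 41 (40 higher, 1 lower), and the cause was not tested. The covariate used the labelled sexes, which the Y-linked counts contradict. Leaving out 1 library gave 27 to 3492 calls, 25 to 1851 higher and 1 to 1641 lower, in fits with 1 residual degree of freedom where the lone library is assumed to vary like the other group. All 11 genes were called under each alternative, except with limma-voom (8) and without control replicate 8 (10). The Adar log2 fold change stayed positive, from 0.45 to 1.06 when 1 library was left out, and it passed without knockout-labelled replicate 1 (adjusted p = 0.0130, range over the alternatives 0.0130 to 0.9999). The 21 list calls of camera became 0 with an estimated correlation and 0 with fry. Both of these rest on 2 residual degrees of freedom, so the loss does not show that the lists are unchanged.

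Among named genes and called lists, direction turned when 1 library was left out, and the cause was not tested. S100a9 ran from -0.0944 (without knockout-labelled replicate 1) to 3.06 and Eif2s3y from -14.5, against the library at 0 counts, to 0.47 (without knockout-labelled replicate 2). The granulocyte list turned lower without knockout-labelled replicate 1 (adjusted p = 0.217, range 2.66e-16 to 0.217 over the fits that leave out 1 library, and 0.653 with an estimated correlation), as did the histone list (0.0112, over those fits 6.21e-20 to 0.0112, and 0.653), and the hepatocyte list turned higher without control replicate 3 (0.847, over those fits 3.01e-07 to 0.847, and 0.653). Of 534 alternative values of the 41 named genes, 462 kept direction and side of the threshold, 67 newly passed and 3 no longer passed. Of 248 for the list tests, 193 kept the side of the threshold, 49 no longer passed and 3 newly passed. Direction also turned in lists that passed neither way: the haem list (adjusted p = 0.733) and the erythroid membrane list (0.847) without control replicate 3, the erythroid transcription factors without knockout-labelled replicate 1 (0.912), and cell death without knockout-labelled replicate 1, 2 or control replicate 3 (0.817, 0.992, 0.853) and with fry (0.452). The groups share no replicate number, so libraries were not paired by it. The only blocking was by labelled sex, in the fit with sex as a covariate.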

Other observations

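Tests chosen only after the result was seen were those of the granulocyte reads, the S-phase genes, both tests of the macrophage genes and the ratio of the Y-linked values in control replicate 3. Replication-dependent histone genes were 21, of which 0 passed over all genes or adjusted over the list alone in edgeR's quasi-likelihood test, where DESeq2 gave 7 higher and 1 lower over the list alone. Hist1h1e had 40.9 CPM in knockout-labelled replicate 1 and 2.18, 2.18 and 2.51 in knockout-labelled replicate 2 and the controls. Hist1h1a had 24.5 against 1.45, 1.23 and 1.46 in the same order. The list median was 3.11 in knockout-labelled replicate 1 and -0.17 in replicate 2 (camera adjusted p = 0.00555, higher). With an estimated correlation that adjusted p = 0.653, and without knockout-labelled replicate 1 the list lay lower (adjusted p = 0.0112). Hist1h1c, a linker histone gene, went the other way, with 132 and 145 CPM in the knockout-labelled libraries and 229 and 275 in the controls (log2 fold change -0.87, SE 0.20, adjusted p = 0.28).

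Knockout-labelled replicate 1 stood apart from the other libraries across genes. Its Pearson r of log2 values across genes was 0.956 with knockout-labelled replicate 2, 0.909 with control replicate 3 and 0.93 with control replicate 8, while the controls had 0.988 with each other, and genes are not independent replicates. The first principal component held 78.2% of the variance and placed knockout-labelled replicate 1 at 65.7, replicate 2 at 3.66 and the controls at -43.5 and -25.9.

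Granulocyte and histone genes were both higher in knockout-labelled replicate 1 alone, and no biological explanation other than more cells in S phase was tested, since the design gives this library no group of its own. All 10 granulocyte genes, of which 0 are on another list, lay above the mean of the other libraries, by a median of 2.89 on the log2 scale (S100a9 at 113 CPM and Ngp at 68.5 were the most abundant), with an SD of 0.818 between them. Reads from granulocytes, which the sort for YFP would remove, stay open as a candidate source, since the bound on that SD was set after the pattern was seen. The granulocyte median was 2.87 after a linear fit on GC content and transcript length, and the histone median was 2.95 after that fit and 2.92 before (19 of 21 genes). This argues against a linear effect of GC content or length across all genes as the whole cause. A nonlinear effect was not tested. More cells in S phase would raise the S-phase list, and its median in this library was -0.52 (SE 0.0798, 2 of 30 genes above the other libraries), while reads shared between histone paralogs or a difference in the capture of transcripts without a poly(A) tail were not tested and stay open.

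The macrophage list had medians below the control mean in both knockout-labelled libraries (-1.78 and -0.84), with C1qa at 0.196 and 0.803 CPM against 3.55 and 1.67. C1qa and Vcam1 exceeded 1 CPM only in the controls and are in the table through them. A list median that includes such genes can lean lower for that reason. Fewer cells of every other type in these sorts would lower endothelial genes too. The endothelial median was 2.24 above the macrophage median (permutation p = 0.0009, over genes). That permutation treats genes of the same libraries as independent, so its p does not measure the spread between libraries. The endothelial medians were 0.24 and 1.08 in knockout-labelled replicates 1 and 2, so this list did not fall in either. The hepatocyte median was -0.57, but 0.20 without control replicate 3, so it decides nothing here. Camera's call of the macrophage list as lower (adjusted p = 4.09e-05) was lost with an estimated correlation (adjusted p = 0.615). Without control replicate 3 Vcam1 was at -1.77, and the macrophage median was -0.66 with a standard error of 0.301. How much of the pattern a high control replicate 3 carries therefore cannot be told apart from a difference between groups. The knockout itself stays open as a biological explanation.

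The Y-linked counts went against the sex labels of both knockout-labelled libraries and of control replicate 3. If the sex labels of the knockout-labelled libraries had been exchanged, X-linked genes that escape inactivation would be highest in replicate 2. Of 4 such genes, 2 were. That ranking cannot decide, because Kdm6a and Kdm5c were also higher in knockout-labelled replicate 1 (257 and 381 CPM) than in the controls. Control replicates 3 and 8 had 150 and 129 CPM of Kdm6a and 237 and 243 of Kdm5c. The exchange therefore cannot be told apart from other causes. The Y-linked values of control replicate 3 were 0.836 of those of control replicate 8 (0.770 at 1 standard error lower). The genes ranged from 0.681 to 0.997. If male cells express these genes alike, reads of a male embryo carried into control replicate 3 would have to be most of that library. Carry-over of that size cannot be told apart from a wrong label. Sex of the embryos is not a group of the comparison, but by these counts it was not balanced between the groups. Both controls had Y-linked reads (5599 and 10695 counts), while knockout-labelled replicate 1 had 11705 and replicate 2 had 3. No biological explanation was tested.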
